A study of Homo sapiens with 24 samples.

How the data were processed

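Poly(A) RNA of cultured human umbilical vein endothelial cells was sequenced after 1, 4, 12 or 24 h of static culture, pulsatile flow or oscillatory flow. The 12 groups of flow and time had 2 libraries each, and per the labels the replicate number is a batch, so each of the 2 batches held 1 library of every group (12 libraries). Per the labels the cells grew on collagen I, RNA was taken with TRIzol and libraries were made with a TruSeq kit. The deposited raw table holds counts, whole numbers of reads per gene from STAR and HTSeq on hg19 per the submitters' processing notes. Tool versions, the annotation release and the strand setting were not stated, so reads on the opposite strand, such as those of an antisense transcript overlapping *CYP1B1*, could not be set apart, nor could reads shared between paralogs. The deposited transformed table holds log2 values after the authors' variance stabilizing transformation. A deposited DESeq2 table for pulsatile against oscillatory flow at 24 h holds, per the file headers, log2 fold changes, a normalized mean signal (the mean over samples of counts divided by size factors) and each p-value, raw and adjusted. Its per-sample columns, named as counts, hold values on a log2 scale in the authors' table, without a named transformation, and were not used. The authors' design formula for that table was not stated. The comparisons here started from the counts. GC share and gene length came from an annotation on another genome build, matched by gene identifier without its version, and no coordinates are given.

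The count table held 23839 genes. Genes of chromosome Y and the X-inactivation transcripts, 25 in all, were left out because the cells come from human donors, and 21507 genes passed edgeR's filterByExpr (a minimum count of 10 and a minimum total of 15). Library totals ran from 39159890 to 65870784 counts. These reads carried no molecular identifiers, so their number limits counting error only, and the 2 libraries per group limit the precision more. Counts were normalized with TMM and fitted with edgeR 4.0.16 quasi-likelihood models in R 4.3.3, with 1 mean per group over all 24 libraries and no batch term. The F test, contrasts between flows at each time, contrasts of 24 h against 1 h and the shift in the pulsatile minus oscillatory difference used that fit. Comparisons over all times used the 16 libraries of the flows compared, 8 against 8, with time as a term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM are counts scaled to a common library size, log2 CPM used a prior count of 2, and SE is the standard error of the fitted change. These choices, the gene lists and the alternatives were set before the data were examined, except those named as added.

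Batch pairs the libraries: the pairing comes from the labels, and in a check on the counts the deviations between the libraries of a group correlated across genes at 0.68 to 0.89 between groups (median 0.80, 66 pairs of groups). The fit with batch as a term was set as a second analysis before the data were examined, and its values stand beside or in place of those without it wherever calls changed. Simulated data had the library sizes of the real data, with 100 genes changed by 1 log2 unit and 100 by 2 under pulsatile flow at 24 h. For pulsatile against oscillatory flow, the fit without a batch term recovered 0% of changes of 1 log2 unit and 19% of changes of 2. The fit with batch recovered 64% and 86%, with 13 false calls over both sizes together. The data were drawn from a model with a batch term and no GC or length trend of single libraries, so the gain from that term was built in.

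The 32 gene lists were fixed before the data were examined. Flow and vessel lists were shear-protective genes, NF-kB and leukocyte adhesion, endothelial identity, vasoactive pathways, Notch and arterial genes, TGF-beta and BMP signalling, YAP and TAZ targets, angiogenesis and tip cells, coagulation, extracellular matrix, mesenchymal transition, actin and SRF targets, and mechanosensors. Cell state lists were NRF2 targets, cholesterol, mitosis, DNA replication, immediate early genes, unfolded protein and amino acid response, hypoxia and glycolysis, interferon, heat shock, circadian clock, p53, autophagy, mitochondrial biogenesis, histones and mitochondrially encoded RNA. Markers of leukocytes, red cells, smooth muscle or fibroblasts, and epithelium stood for other cells. Lists were tested with camera (limma 3.58.1) on log2 CPM at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison.

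Genes were named by a fixed rule. A panel of 16 flow-responsive genes (*KLF2*, *KLF4*, *NOS3*, *THBD*, *VCAM1*, *ICAM1*, *CCL2*, *EDN1*, *ANGPT2*, *HMOX1*, *NQO1*, *ID1*, *CYR61*, *CTGF*, *SMAD6*, *DLL4*) was given for pulsatile against oscillatory flow whether or not it passed. Next came the genes with the largest changes past the threshold, with a mean of at least 2 log2 CPM and the same sign in both batches: 5 per direction for pulsatile against oscillatory flow and over all times, 3 per direction otherwise, and for the F test the 8 with the smallest p. Last came up to 4 members of each list described, which were lists past the camera threshold or with 25% or more of their members past it. The use of the same rule in the fit with batch, the panel genes named against static culture, the highest markers of other cells and the aryl hydrocarbon receptor genes were chosen after the values were seen. Some genes that the rule picked are not reported here.

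The analyses repeated with other settings, as set before the data were examined, were the batch term, DESeq2 size factors, DESeq2 1.42.0 Wald tests (a likelihood ratio test for the F test), no filter, a stricter filter (1 CPM in 4 libraries and a mean of 50 counts), the 4 libraries of a comparison alone, a time-averaged contrast of the 24 libraries, an absolute log2 fold change of at least 1, a prior count of 0.5 and leaving out each library of the groups compared. Offsets that remove each library's trend with GC share and gene length (splines with 5 degrees of freedom each), alone or with batch, and the other alternatives run with batch as a term were added after seeing the data. The overlap of the comparisons with static was set beside 20 simulations of unchanged groups and beside static libraries split by batch. Other splits of the libraries were counted over 100 draws. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.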

Results

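Human umbilical vein endothelial cells were kept static or exposed to pulsatile or oscillatory flow for 1, 4, 12 or 24 h, with 2 libraries per group, one from each of 2 batches. Pulsatile flow had a mean shear stress of 12 dyn/cm2 and oscillatory flow a mean of 0.5 dyn/cm2, each with an amplitude of 4 dyn/cm2. Pulsatile flow stands for the arterial regions that resist atherosclerosis and oscillatory flow for the regions prone to it. The 24 libraries held 39159890 to 65870784 counts (median 48213304). The batches differed across the whole transcriptome: the first principal component, with 56.7% of the variance, separated them, and the second held 12.4%. Changes below are log2 fold changes ± SE from edgeR with n = 2 libraries per group. Unless a sentence says otherwise they come from the fit with batch as a term, and adjusted p-values are Benjamini-Hochberg values. The counts of the planned fit, which had no batch term, stand beside those with batch as a term. Largest rises and falls are those of genes above an expression floor that changed the same way in both batches. For gene lists, the first camera p-value is that of the fit without a batch term and a preset correlation between genes, the second that with an estimated correlation. Where a list passed with both, the third adds batch to the estimated correlation.

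**Figure D1:**
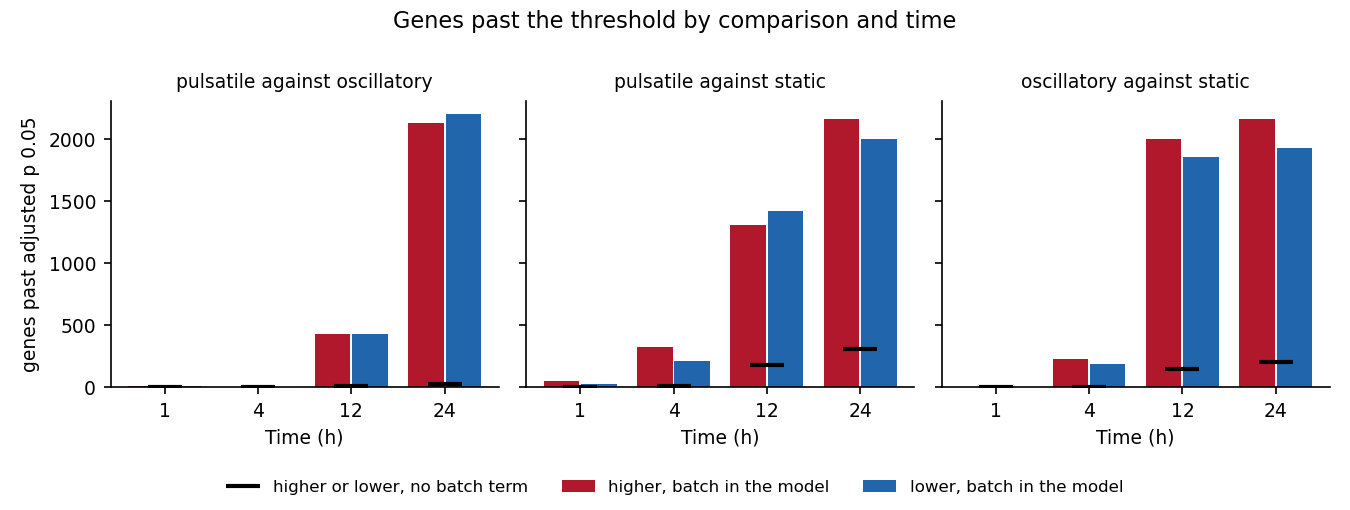
Number of genes past an adjusted p of 0.05 (y axis) at each time in hours (x axis) for each pair of flows, with bars for genes higher and lower when batch was in the model and a black mark for all genes past the threshold without a batch term. Pulsatile against oscillatory flow went from 3 genes at 4 h to 4332 at 24 h with batch in the model.

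After 1 h, *PDE4B*, a phosphodiesterase that degrades cAMP, was lower under pulsatile than oscillatory flow (-1.56 ± 0.21, adjusted p = 0.0162), as were the axon-guidance semaphorin *SEMA6D* (-1.29 ± 0.20), *FAM84B* (-1.26 ± 0.22), *CREBRF* (-1.09 ± 0.18) and *YPEL2* (-1.02 ± 0.16). *FAM212A* (1.47 ± 0.26), the ubiquitin ligase *TRIM47* (0.90 ± 0.16) and *FAM109A* (0.85 ± 0.15) were higher. The shear-responsive transcription factors *KLF2* (1.73 ± 0.40, adjusted p = 0.095) and *KLF4* (1.08 ± 0.22, adjusted p = 0.0712) did not pass the test at this time. No panel gene passed: *NOS3*, *THBD*, *VCAM1*, *ICAM1*, *CCL2*, *EDN1*, *ANGPT2*, *HMOX1*, *NQO1*, *ID1*, *CYR61*, *CTGF*, *SMAD6* and *DLL4* had adjusted p-values of 0.136 or more. The mitochondrially encoded RNAs had a median change of 0.57 (camera adjusted p = 1.82e-06, adjusted p = 0.235 with an estimated correlation), with 0.70 in batch 1 and 0.34 in batch 2. The NF-kB and mesenchymal lists passed with the preset correlation only (adjusted p = 0.915 and adjusted p = 0.234 with an estimated correlation). In the fit without batch edgeR called 0 genes, with 247 at an unadjusted p under 0.05, and DESeq2 called 0. In the fit with batch, 14 passed (5 higher and 9 lower) in edgeR and 1047 in DESeq2. With GC and length offsets as well, 3 passed, *PDE4B* (adjusted p = 0.012) and *YPEL2* (adjusted p = 0.0328) among them. The third was *HR*, below the expression floor for naming and chosen after its values were seen.

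After 4 h the shear-protective genes stood higher under pulsatile than oscillatory flow. *KLF4*, a transcription factor induced by laminar shear, rose (1.98 ± 0.22, adjusted p = 8.36e-04), 2.13 in batch 1 and 1.85 in batch 2. *PTGIS*, the prostacyclin synthase, rose (1.24 ± 0.19, adjusted p = 0.0288), as did *TSC22D3*, a glucocorticoid-induced leucine zipper protein (1.05 ± 0.15, adjusted p = 0.0156). These were the 3 genes past the threshold with batch as a term. Among the shear-protective genes, 2 of 19 rose (9 passed when adjusted over the list alone), 17 were higher in both batches and the list's median change was 0.63 (camera adjusted p = 4.09e-16, 0.00349 and 0.00325). *KLF2* (1.35 ± 0.40, adjusted p = 0.613), *NOS3* (0.63 ± 0.16), *THBD* (0.52 ± 0.22) and *ANGPT2* (-0.52 ± 0.19) did not pass. Nor did the other panel genes *VCAM1* (-0.62 ± 0.59), *ICAM1* (0.13 ± 0.41), *CCL2* (-0.71 ± 0.54), *EDN1* (-0.38 ± 0.14), *HMOX1* (0.47 ± 0.35), *NQO1* (0.09 ± 0.18), *ID1* (0.06 ± 0.38), *CYR61* (-0.38 ± 0.16), *CTGF* (-0.39 ± 0.14), *SMAD6* (-0.10 ± 0.29) and *DLL4* (0.47 ± 0.35). No other list passed. With batch left out edgeR called 0 genes, with 133 at an unadjusted p under 0.05, and DESeq2 called 0, or 43 with batch as a term. With GC and length offsets and batch, 8 genes passed.

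By 12 h more genes differed between pulsatile and oscillatory flow. Without a batch term *CD34*, a sialomucin of endothelial and progenitor cells, was higher by 3.57 ± 0.42, adjusted p = 0.00359 (3.50 in batch 1 and 3.61 in batch 2). The chemokine-scavenging receptor *ACKR4* (2.90 ± 0.40), the laminin-binding integrin subunit *ITGB4* (2.47 ± 0.34), the efflux transporter *ABCG2* (1.96 ± 0.32) and the Rac regulator *CHN1* (1.13 ± 0.18) were higher as well without that term. *ANGPT2*, a ligand of the Tie2 receptor that loosens vessels, changed by -2.13 ± 0.27, adjusted p = 0.00649 without a batch term (-2.34 in batch 1 and -1.96 in batch 2). Once batch was in the model the prostaglandin transporter *SLCO2A1* (2.64 ± 0.24), the natriuretic peptide receptor *NPR1* (2.50 ± 0.26) and *APOL1* (2.65 ± 0.50) joined the largest rises. *RGCC* (-1.98 ± 0.39), the filamin-binding *FILIP1* (-1.83 ± 0.17), the acyl-CoA synthetase *ACSM3* (-1.79 ± 0.27) and the sulfotransferase *SULT1C4* (-1.71 ± 0.39) followed *ANGPT2* among the largest falls.

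Among the shear-protective genes at 12 h, 13 of 19 rose (17 passed when adjusted over the list alone). The list's median was 1.34 (1.47 in batch 1 and 1.11 in batch 2, camera adjusted p = 3.61e-21, 9.83e-04 and 0.00236). *KLF4* (2.09 ± 0.22), *KLF2* (1.46 ± 0.40), the nitric oxide synthase *NOS3* (1.00 ± 0.16), the anticoagulant thrombomodulin *THBD* (1.28 ± 0.22), the scaffold protein *SLC9A3R2* (2.24 ± 0.19) and the arginine-recycling enzyme *ASS1* (1.74 ± 0.26) rose. The vasoconstrictor gene *EDN1* (-0.50 ± 0.14) and the YAP target *CTGF* (-0.53 ± 0.14) fell. *CYR61* (-0.56 ± 0.16), *VCAM1* (-1.42 ± 0.61), *ICAM1* (-0.10 ± 0.41), *CCL2* (-0.41 ± 0.54), *HMOX1* (1.13 ± 0.35), *ID1* (0.66 ± 0.38), *SMAD6* (-0.09 ± 0.30) and *DLL4* (0.17 ± 0.29) did not pass. The antioxidant enzyme *NQO1* (0.94 ± 0.18) rose. Of 26 mitosis genes 5 fell, among them *CENPE* (-0.88 ± 0.21) and *ASPM* (-0.86 ± 0.21), with a median of -0.50 (camera adjusted p = 9.97e-06, adjusted p = 0.421 with an estimated correlation). Of 20 vasoactive genes 6 rose and 3 fell (camera adjusted p = 0.0793, adjusted p = 0.365 with an estimated correlation), with *PTGIS* (0.99 ± 0.19) and *GCH1* (0.89 ± 0.23) among the rises. The endothelial identity list had a median of 0.24 (camera adjusted p = 0.00859, adjusted p = 0.162 with an estimated correlation), with *ICAM2* (1.21 ± 0.24) and *ESAM* (0.62 ± 0.14) higher. The YAP and TAZ, Notch, actin, NF-kB, interferon and histone lists passed with the preset correlation only (adjusted p = 0.365, adjusted p = 0.421, adjusted p = 0.365, adjusted p = 0.791, adjusted p = 0.863 and adjusted p = 0.637 with an estimated correlation).

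In the fit without batch, 12 genes passed at 12 h (10 higher and 2 lower), with batch as a term 857 (431 and 426), and 650 with GC and length offsets as well. The changes followed GC share (Spearman 0.49 across 10488 genes, which are not independent replicates) and gene length (-0.42). Of 806 called genes with a GC value, 466 still passed with the same sign. With those offsets *KLF2* (1.08, adjusted p = 0.155), *CENPE* and *ASPM* no longer passed, and *CYR61* (-0.65, adjusted p = 0.0108) newly passed.

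At 24 h the separation was widest. With batch left out *CD34* rose by 3.55 ± 0.41, adjusted p = 0.00227, from 12.4 ± 7.86 under oscillatory to 145 ± 13.7 CPM under pulsatile flow (mean ± SD, n = 2). In the same fit *ASS1* rose by 3.09 ± 0.37, adjusted p = 0.00246, and *ACKR4* (2.90 ± 0.40), *ABCG2* (2.74 ± 0.33) and *ITGB4* (2.73 ± 0.34) rose as well. Also without a batch term, *ANGPT2* fell by 2.91 ± 0.28, adjusted p = 3.97e-04, from 46.9 ± 2.27 to 6.23 ± 1.26 CPM, with -2.66 in batch 1 and -3.17 in batch 2, and *ACSM3* (-1.84 ± 0.30) fell. After adding batch *SLCO2A1* (3.55 ± 0.25) and *APOL1* (2.86 ± 0.49) were also among the largest rises. *FAM196B* (-3.11 ± 0.79), *KIAA0754* (-3.05 ± 0.87), the palmitoyltransferase *ZDHHC20* (-2.23 ± 0.63) and the stem cell factor receptor *KIT* (-2.07 ± 0.29) were among the largest falls.

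The shear-protective genes rose together at 24 h: 15 of 19 rose (16 passed when adjusted over the list alone). The list's median was 1.63 (1.61 in batch 1 and 1.65 in batch 2, camera adjusted p = 1.56e-14, 0.0055 and 0.0116). *KLF2* (1.94 ± 0.41), *KLF4* (2.21 ± 0.22), *NOS3* (1.28 ± 0.17), *THBD* (1.58 ± 0.22), *SLC9A3R2* (2.56 ± 0.19) and *CYP1B1* (2.30 ± 0.46) were among them. In the vasoactive list, 7 of 20 rose and 6 fell (14 passed when adjusted over the list alone). Its rises included *NPR1* (2.69 ± 0.26) and *GCH1* (1.13 ± 0.23), the first enzyme of the pathway to the nitric oxide cofactor tetrahydrobiopterin, and its falls *PDE4B* (-1.22 ± 0.21). Among the NRF2 targets, 10 of 20 rose and 1 fell (14 passed when adjusted over the list alone). *NQO1* (1.56 ± 0.18), *FTL* (1.47 ± 0.28), *PIR* (1.13 ± 0.17) and *HMOX1* (1.27 ± 0.35) rose. The list's median was 0.54 (camera adjusted p = 0.0331, adjusted p = 0.644 with an estimated correlation). In the endothelial identity list, 6 of 22 rose (6 passed when adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.162 with an estimated correlation). *ICAM2* (1.59 ± 0.24), *CLDN5* (1.33 ± 0.40) and *EGFL7* (0.94 ± 0.27) rose. The arterial genes *GJA4* (1.04 ± 0.34), *GJA5* (0.99 ± 0.33) and *JAG2* (0.97 ± 0.15) rose while *CXCR4* (-1.43 ± 0.26) fell. In that Notch and arterial list, 4 of 17 rose and 1 fell (5 passed when adjusted over the list alone, camera adjusted p = 0.142, adjusted p = 0.647 with an estimated correlation).

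In the YAP and TAZ list at 24 h, 8 of 23 fell (9 passed when adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.6 with an estimated correlation). *F3* (-1.83 ± 0.49), the tissue factor that starts coagulation, *IGFBP3* (-1.16 ± 0.37), *DLC1* (-0.84 ± 0.14) and *CYR61* (-0.47 ± 0.16) fell. The tip cell genes *ESM1* (-1.41 ± 0.25) and *FLT1* (-1.01 ± 0.16), the matrix protease *MMP10* (-1.20 ± 0.20), N-cadherin *CDH2* (-1.38 ± 0.14), the integrin subunits *ITGB3* (-1.48 ± 0.41) and *ITGB1* (-0.90 ± 0.24) and *EDN1* (-0.50 ± 0.14) fell. Of the immediate early genes *EGR1* (-1.48 ± 0.31) and *KLF6* (-0.87 ± 0.18) fell and *DUSP5* (0.78 ± 0.21) rose. Among the mitosis genes, 7 of 26 fell (7 passed when adjusted over the list alone), with *CENPE* (-1.04 ± 0.22), *ASPM* (-1.04 ± 0.21) and *MKI67* (-0.91 ± 0.22) lower (camera adjusted p = 0.0101, adjusted p = 0.647 with an estimated correlation), and the list's medians were -0.04 in batch 1 and -0.84 in batch 2. The BMP receptor *ACVRL1* (0.83 ± 0.13) and its target *ID1* (1.23 ± 0.39) rose. The panel genes *VCAM1* (-1.05 ± 0.58), *ICAM1* (0.09 ± 0.41), *CCL2* (-0.53 ± 0.54), *CTGF* (-0.30 ± 0.14), *SMAD6* (0.06 ± 0.30) and *DLL4* (0.28 ± 0.28) did not pass, and of 25 NF-kB and adhesion genes none did (median -0.73, camera adjusted p = 0.0223, adjusted p = 0.738 with an estimated correlation).

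In the other lists at 24 h members moved both ways or few passed. As counts of genes higher and lower, the hypoxia and glycolysis list had 4 and 3 of 24, autophagy 4 and 2 of 17, p53 4 and 0 of 18, the unfolded protein and amino acid response 1 and 2 of 21, heat shock 2 and 0 of 14, the circadian clock 0 and 4 of 16, mechanosensors 4 and 4 of 21, mitochondrial biogenesis 2 and 2 of 16 and actin 1 and 1 of 15. Matrix had 3 and 8 of 28, coagulation 3 and 4 of 18, angiogenesis 4 and 5 of 26, mesenchymal transition 2 and 2 of 15, interferon 2 and 0 of 27, replication 0 and 5 of 26, cholesterol 4 and 0 of 24, mitochondrially encoded RNA 0 and 3 of 13 and histones 2 and 0 of 7. The histone list passed with the preset correlation only (adjusted p = 0.644 with an estimated correlation). The stress-induced mTOR inhibitor *DDIT4* (1.86 ± 0.22), *NDRG1* (1.03 ± 0.23) and the lysosomal protease *CTSD* (1.15 ± 0.18) rose, and the glycolytic regulators *HK2* (-0.79 ± 0.20) and *PDK1* (-0.81 ± 0.14) fell.

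Without a batch term, 22 genes passed at 24 h (19 higher and 3 lower), and with batch as a term 4332 (2132 and 2200). The changes followed GC share (Spearman 0.49 across 10488 genes, which are not independent replicates) and gene length (-0.51). With GC and length offsets and batch 2764 genes passed (1339 higher and 1425 lower). Of 3996 called genes with a GC value, 1927 still passed with the same sign, and the median absolute change of the called genes went from 0.74 to 0.47. *HMOX1*, *CLDN5*, *EGFL7*, *GJA4*, *DUSP5*, *ASPM*, *MKI67*, *ID1* and *PDK1* no longer passed with the offsets, and *KIAA0754* and *GJA5* had no GC value. *CTGF* (-0.52, adjusted p = 0.0092) newly passed.

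**Figure D2:**
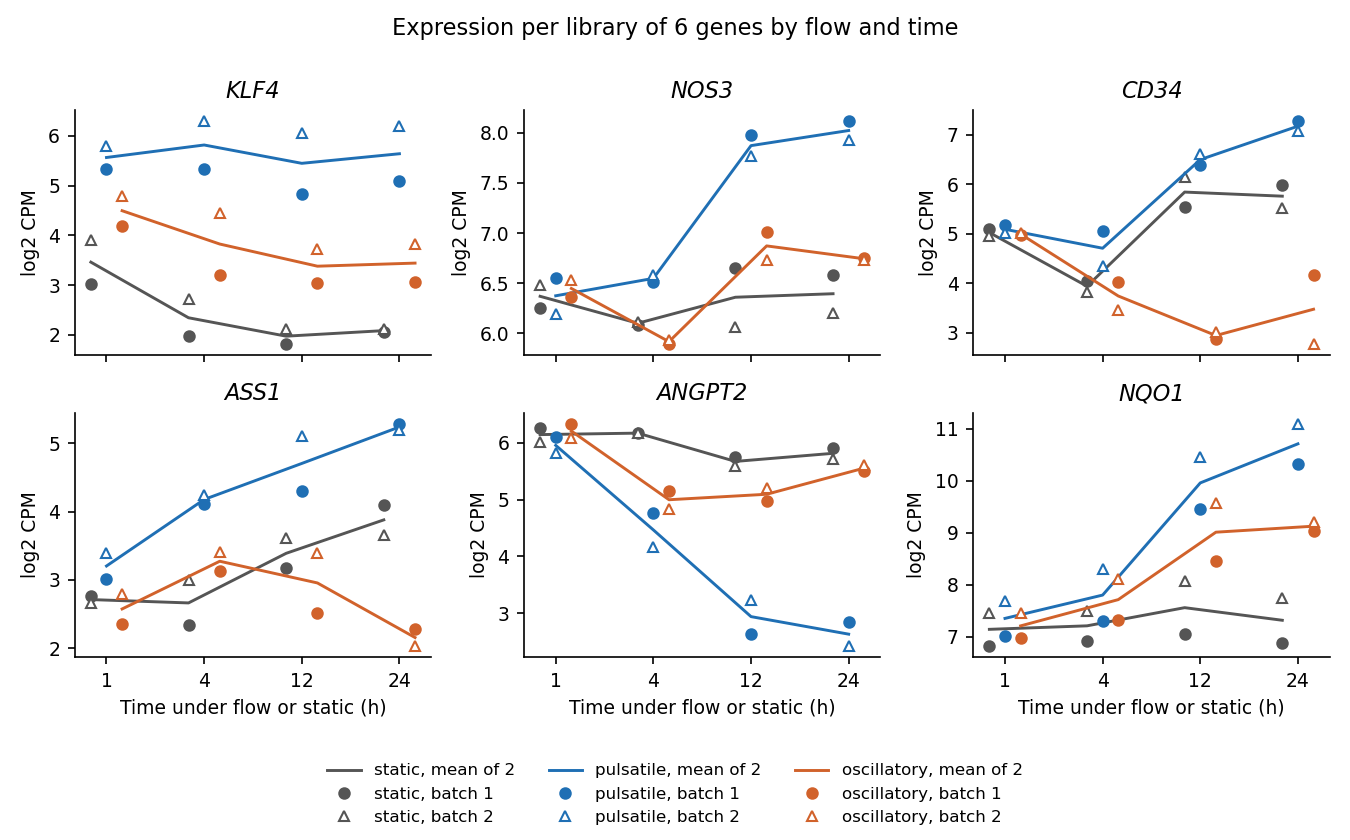
Expression in log2 CPM (y axis) of 6 genes at each time in hours (x axis), with 1 point per library (circles for batch 1, triangles for batch 2) and lines through the mean of the 2 libraries of each flow. *ANGPT2* fell to 6.23 CPM under pulsatile flow at 24 h, against 46.9 CPM under oscillatory flow.

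The authors' deposited DESeq2 table of this comparison called 4900 genes at an adjusted p under 0.05, 2228 higher and 2672 lower under pulsatile flow. Of 4894 of these tested here, 4086 passed with batch as a term, all of them with the same sign, and 22 without it. The log2 fold changes of the deposited table and of the fit with batch correlated at r = 0.87 across genes. In the deposited table *CD34* changed by 3.11, *ANGPT2* by -2.74, *KLF4* by 2.01 and *NOS3* by 1.19.

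Averaged over the 4 times, *CD34* (2.06 ± 0.45), *SLCO2A1* (1.87 ± 0.35), *KLF4* (1.83 ± 0.15), *NPR1* (1.80 ± 0.25) and *CYP1B1* (1.70 ± 0.20) had the largest rises under pulsatile against oscillatory flow. *ANGPT2* (-1.43 ± 0.31), *KIT* (-1.31 ± 0.21), *F3* (-1.20 ± 0.25), *FILIP1* (-1.16 ± 0.17) and *RGCC* (-1.15 ± 0.28) had the largest falls. *KLF2* (1.65 ± 0.15), *NOS3* (0.71 ± 0.14), *THBD* (0.86 ± 0.19), *HMOX1* (0.94 ± 0.14) and *NQO1* (0.68 ± 0.18) rose and *EDN1* (-0.37 ± 0.08), *CYR61* (-0.35 ± 0.10) and *CTGF* (-0.34 ± 0.08) fell. *VCAM1* (-0.83 ± 0.28), *ICAM1* (0.11 ± 0.18), *CCL2* (-0.21 ± 0.27), *ID1* (0.60 ± 0.19), *SMAD6* (0.08 ± 0.13) and *DLL4* (0.44 ± 0.17) did not pass. Among the shear-protective genes, 15 of 19 rose (17 passed when adjusted over the list alone). These values compare 8 libraries with 8. In the fit without batch, 0 genes passed, with 1066 at an unadjusted p under 0.05, and DESeq2 called 134. With batch as a term, 1602 passed (723 higher and 879 lower). With GC and length offsets as well, 719 passed.

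The difference between pulsatile and oscillatory flow grew over time for a few genes. Between 1 and 24 h it shifted by 3.15 ± 0.46, adjusted p = 0.0288 for *ITGB4*, 3.06 ± 0.45, adjusted p = 0.0288 for *ABCG2* and -2.66 ± 0.37, adjusted p = 0.0205 for *ANGPT2*, without a batch term. In the fit with batch *CD34* (3.50 ± 0.42), *SLCO2A1* (3.41 ± 0.33) and *ACKR4* (2.97 ± 0.46) shifted upward. The chemokine *CCL14* (-2.65 ± 0.48), the interleukin *IL11* (-1.96 ± 0.44), the arginine transporter *SLC7A2* (-1.65 ± 0.23) and *MEX3A* (-1.60 ± 0.23) shifted downward. In an F test of the difference over the 4 times, *ANGPT2* (adjusted p = 0.0397) and *ABCG2* (adjusted p = 0.0397) passed without a batch term. Without that term their pulsatile minus oscillatory changes at 1, 4, 12 and 24 h were -0.25, -0.51, -2.13, -2.91 for *ANGPT2* and -0.32, -0.22, 1.96, 2.74 for *ABCG2*. *CD34* (adjusted p = 0.0547), *ITGB4* (0.0622), *ACKR4* (0.103) and *CHN1* (0.27) missed the threshold without a batch term, as did *C1QTNF6*, *LIMS2*, *SLCO2A1*, *SLC9A3R2*, *ASS1* and *CCDC69*. All 10 passed with batch as a term (adjusted p from 1.84e-05 to 0.00593). The shift between 1 and 24 h passed for 6 genes without a batch term and 187 with it (134 upward and 53 downward). The F test passed for 4 and 545 genes. The other genes of those 4, *AQP1* and *ST6GALNAC1*, lay below the expression floor for naming and were chosen after their values were seen.

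After 1 h of pulsatile flow against static culture, *KLF4* (2.11 ± 0.22, adjusted p = 1.75e-04), *KLF2* (2.12 ± 0.41, adjusted p = 0.0231) and the dioxin-inducible monooxygenase *CYP1B1* (2.42 ± 0.49, adjusted p = 0.0311) had the largest rises. *C10orf10* (-2.88 ± 0.50), the potassium channel *KCNJ2* (-1.88 ± 0.37) and *PDE4B* (-1.81 ± 0.22) had the largest falls. Among the immediate early genes, 7 of 20 rose (16 passed when adjusted over the list alone). *JUNB* (1.72 ± 0.31), *NR4A1* (1.60 ± 0.25) and *IER3* (0.91 ± 0.17) rose. The list's median was 0.90 (1.22 in batch 1 and 0.51 in batch 2, camera adjusted p = 1.81e-28, 1.73e-04 and 0.0563). The Notch genes *HEY1* (1.81 ± 0.26), *DLL4* (1.60 ± 0.29) and *NRARP* (1.00 ± 0.20) rose (list median 0.54, camera adjusted p = 1.25e-05, adjusted p = 0.094 with an estimated correlation). The heat shock, shear-protective, NF-kB, mesenchymal and mitochondrially encoded RNA lists passed with the preset correlation only (adjusted p = 0.179, adjusted p = 0.261, adjusted p = 0.725, adjusted p = 0.0955 and adjusted p = 0.188 with an estimated correlation). With batch left out, 0 genes passed, with 261 at an unadjusted p under 0.05, and DESeq2 called 22. Once batch was in the model, 76 passed (50 higher and 26 lower). The changes followed GC share (Spearman 0.50 across 10488 genes, which are not independent replicates) and gene length (-0.63). With GC and length offsets and batch, 54 passed, and *KLF2*, *IER3* and *NRARP* no longer did.

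After 4 h of pulsatile flow, without a batch term, the prostaglandin synthase *PTGS2* (2.70 ± 0.43), the TGF-beta target *PMEPA1* (1.38 ± 0.19) and the glutathione synthesis gene *GCLM* (1.37 ± 0.21) were higher than in static cells. The ligands *BMP4* (-1.81 ± 0.28) and *ANGPT2* (-1.67 ± 0.26) and the GTPase *GIMAP8* (-1.52 ± 0.24) were lower in that fit. After adding batch *CYP1B1* (4.94 ± 0.55), the heme oxygenase *HMOX1* (4.26 ± 0.40) and the Notch effector *HEY1* (3.84 ± 0.31) had the largest rises. *KIT* (-3.38 ± 0.32), *C10orf10* (-3.27 ± 0.47) and *PPP1R16B* (-2.65 ± 0.17) had the largest falls. Among the shear-protective genes, 9 of 19 rose (12 passed when adjusted over the list alone, camera adjusted p = 4.73e-18, 0.00208 and 0.00209). *KLF4* (3.49 ± 0.24) and *PTGIS* (1.56 ± 0.20) rose. In the NRF2 list, 6 of 20 rose (7 passed when adjusted over the list alone, camera adjusted p = 4.04e-08, 0.0485 and 0.0267). *OSGIN1* (1.52 ± 0.24) and *SLC7A11* (1.08 ± 0.18) rose. In the TGF-beta and BMP list, 5 of 21 rose and 1 fell (16 passed when adjusted over the list alone, camera adjusted p = 9.90e-08, 0.00293 and 0.0267). The inhibitors *SMAD6* (2.23 ± 0.31) and *SMAD7* (2.13 ± 0.26) and *ID2* (1.57 ± 0.28) rose. In the Notch and arterial list, 6 of 17 rose and 2 fell (13 passed when adjusted over the list alone, camera adjusted p = 4.04e-08, 0.0193 and 0.0763). *HEY2* (2.27 ± 0.29) and *UNC5B* (1.87 ± 0.34) rose and *DLL4* (-1.72 ± 0.32) fell. Among the vasoactive genes 4 rose and 2 fell, *NPR1* (1.91 ± 0.27) and *ADM* (-1.18 ± 0.24) among them (camera adjusted p = 0.0127, 0.0485 and 0.473), and with batch the list no longer passed at the preset correlation either (adjusted p = 0.0902). The heat shock list passed with both correlations (camera adjusted p = 3.56e-05, 0.0485 and 0.175). The replication, matrix, mesenchymal, actin and hypoxia lists passed with the preset correlation only (adjusted p = 0.231, adjusted p = 0.518, adjusted p = 0.066, adjusted p = 0.0645 and adjusted p = 0.395 with an estimated correlation). 9 genes passed without a batch term (4 higher and 5 lower) and 530 with it (321 and 209).

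After 12 h of pulsatile flow *CYP1B1* stood 9.97 ± 1.52 above static culture without a batch term, from a low static level (0.363 ± 0.367 CPM) so the size of its fold depends on the prior count, and *KLF4* (3.61 ± 0.61) and *PTGS2* (3.61 ± 0.45) followed. *C10orf10* (-3.48 ± 0.64), the retinal reductase *DHRS3* (-2.98 ± 0.55) and *ACSM3* (-2.81 ± 0.31) had the largest falls without a batch term. With batch as a term *CYP1A1* (5.50 ± 0.65) and *KIT* (-2.92 ± 0.29) entered those ranks. In the NRF2 list, 17 of 20 rose (17 passed when adjusted over the list alone), with *OSGIN1* (2.80 ± 0.25), *SLC7A11* (2.72 ± 0.19), *HMOX1* (3.66 ± 0.39) and *NQO1* (2.40 ± 0.19) higher (median 1.08, camera adjusted p = 3.17e-16, 0.00667 and 0.00485). Among the shear-protective genes, 15 of 19 rose and 1 fell (17 passed when adjusted over the list alone), with *NOS3* (1.49 ± 0.17) and *PPAP2B* (1.38 ± 0.18) higher (median 1.32, camera adjusted p = 2.26e-16, 0.00185 and 0.00485). Cell cycle genes fell. In the mitosis list, 25 of 26 fell (26 passed when adjusted over the list alone, camera adjusted p = 1.44e-18, 0.0265 and 0.0878). *AURKB* (-2.01 ± 0.24) and *MKI67* (-1.65 ± 0.23) fell. The list's median was -1.22 (-1.18 in batch 1 and -1.32 in batch 2). In the replication list, 25 of 26 fell (26 passed when adjusted over the list alone, camera adjusted p = 3.22e-25, 0.00185 and 0.0681). *RRM2* (-1.89 ± 0.20), *E2F1* (-1.78 ± 0.25) and *MCM2* (-1.40 ± 0.19) fell. Its median was -1.31.

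In the cholesterol list at 12 h of pulsatile flow, 13 of 24 rose and 1 fell (20 passed when adjusted over the list alone, camera adjusted p = 7.61e-09, 0.0291 and 0.135). *INSIG1* (1.73 ± 0.21) and *HMGCS1* (1.49 ± 0.27) rose. In the Notch and arterial list, 8 of 17 rose and 1 fell (9 passed when adjusted over the list alone, camera adjusted p = 6.43e-06, 0.0291 and 0.0878). *HEY2* (3.41 ± 0.33), *JAG2* (1.61 ± 0.15) and *SOX17* (1.71 ± 0.21) rose. In the TGF-beta and BMP list, 10 of 21 rose and 2 fell (17 passed when adjusted over the list alone, camera adjusted p = 4.95e-06, 0.00667 and 0.0878). *ID2* (2.56 ± 0.29), *SMAD6* (2.19 ± 0.32) and *ID1* (1.95 ± 0.40) rose. 7 vasoactive genes rose and 4 fell (camera adjusted p = 5.42e-04, 0.00828 and 0.0878). The matrix and NF-kB lists passed with the preset correlation only (adjusted p = 0.354 and adjusted p = 0.627 with an estimated correlation). The chemokine genes *CXCL1* (-2.41 ± 0.70) and *CCL2* (-1.76 ± 0.55) fell, although *CCL2* no longer passed with GC and length offsets (-1.46, adjusted p = 0.0815), and of 27 interferon genes 9 fell (median -1.06, -0.04 in batch 1 and -1.88 in batch 2; camera adjusted p = 0.128, adjusted p = 0.875 with an estimated correlation). 175 genes passed without a batch term (81 higher and 94 lower) and 2725 with it (1305 and 1420).

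After 24 h of pulsatile flow *CYP1B1* (9.46 ± 1.48), the thrombin receptor family gene *F2RL3* (4.05 ± 0.53) and *PTGS2* (3.80 ± 0.45) had the largest rises over static culture without a batch term. *ANGPT2* (-3.17 ± 0.28), the tight junction gene *CLDN11* (-2.48 ± 0.57) and *C1orf110* (-2.43 ± 0.39) had the largest falls without that term. In the fit with batch *CYP1A1* (5.20 ± 0.64), *CCL14* (-3.52 ± 0.36) and *KIT* (-3.44 ± 0.30) entered those ranks. In the mitosis list, 26 of 26 fell (26 passed when adjusted over the list alone, camera adjusted p = 6.84e-32, 0.00652 and 0.0737). *CDC20* (-2.44 ± 0.24), *CCNB1* (-2.37 ± 0.21) and *PLK1* (-2.24 ± 0.23) fell. This list had a median of -2.20 (-1.47 in batch 1 and -2.85 in batch 2). In the replication list, 25 of 26 fell (25 passed when adjusted over the list alone, camera adjusted p = 1.01e-19, 0.0051 and 0.0738). *TYMS* (-1.71 ± 0.17) and *MCM4* (-1.69 ± 0.16) fell. In the NRF2 list, 17 of 20 rose (19 passed when adjusted over the list alone, camera adjusted p = 3.40e-15, 0.00694 and 0.006). *NQO1* (3.39 ± 0.20) and *HMOX1* (3.08 ± 0.38) rose. Among the shear-protective genes, 16 of 19 rose (16 passed when adjusted over the list alone, camera adjusted p = 4.80e-17, 0.00308 and 0.00572). *KLF4* (3.56 ± 0.24), *KLF2* (1.75 ± 0.41), *NOS3* (1.62 ± 0.17) and *THBD* (1.48 ± 0.22) rose. *ICAM1* (1.71 ± 0.42), an adhesion receptor for leukocytes, rose, *CXCL1* (-2.20 ± 0.70) fell and *VCAM1* (-0.67 ± 0.60) did not pass. *ID2* (2.98 ± 0.29), *HEY2* (3.04 ± 0.33) and *ADAMTS1* (2.23 ± 0.18) were also higher than in static cells. *PHGDH* (-2.06 ± 0.24), the first enzyme of serine synthesis, and *TFAM* (-0.92 ± 0.13), which maintains mitochondrial DNA, fell. In static cells *HEY2* (-3.50 ± 0.33) and *ID2* (-3.35 ± 0.30) fell between 1 and 24 h with batch in the model. A decline in static culture may therefore make up much of their gap at 24 h.

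In other lists at 24 h of pulsatile flow, the TGF-beta and BMP (11 higher, 3 lower; camera adjusted p = 2.01e-04, 0.0133 and 0.127), Notch and arterial (8 and 1; camera adjusted p = 9.58e-07, 0.0182 and 0.0738) and vasoactive (8 and 3; camera adjusted p = 2.01e-04, 0.00652 and 0.0847) lists passed with both correlations, but not once batch was added. The cholesterol (13 and 1), matrix, NF-kB, coagulation, autophagy, histone and leukocyte marker lists passed with the preset correlation only (adjusted p = 0.102, adjusted p = 0.39, adjusted p = 0.656, adjusted p = 0.201, adjusted p = 0.182, adjusted p = 0.3 and adjusted p = 0.0513 with an estimated correlation). 310 genes passed without a batch term (140 higher and 170 lower) and 4163 with it (2160 and 2003).

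With batch in the model, few list calls against static culture held with an estimated correlation. Those that held were the shear-protective and NRF2 calls of pulsatile flow at 4, 12 and 24 h (adjusted p from 0.00209 to 0.0267), its TGF-beta and BMP call at 4 h and the immediate early call of oscillatory flow at 1 h. With GC and length offsets added, the NRF2 call of pulsatile flow at 4 h was lost as well (adjusted p = 0.0573), while the immediate early call of pulsatile flow at 1 h (0.017) and the TGF-beta call of oscillatory flow at 4 h (0.0324) passed. Lost were the immediate early call of pulsatile flow at 1 h, its Notch, vasoactive and heat shock calls at 4 h and its mitosis, replication, TGF-beta, Notch and vasoactive calls at 12 and 24 h, with the cholesterol call at 12 h (adjusted p from 0.0563 to 0.473). For oscillatory flow the TGF-beta and Notch calls at 4 h, the replication, NRF2 and TGF-beta calls at 12 and 24 h and the mitosis call at 24 h were lost (adjusted p from 0.0587 to 0.194).

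Oscillatory flow for 1 h also raised immediate early genes over static culture. In that list, 4 of 20 rose (13 passed when adjusted over the list alone), with *ZFP36* (1.23 ± 0.20, adjusted p = 0.0368) higher. The list's median was 0.79 (0.81 in batch 1 and 0.62 in batch 2, camera adjusted p = 1.34e-45, 1.44e-05 and 0.00281). *KLF4* (1.04 ± 0.22, adjusted p = 0.479) and *KLF2* (0.39 ± 0.40, adjusted p = 1) did not pass. The Notch list passed with the preset correlation only (adjusted p = 0.419 with an estimated correlation). Without a batch term, 0 genes passed, with 107 at an unadjusted p under 0.05, and DESeq2 called 2. Once batch was in the model, 4 passed, all higher: *ZFP36*, *FOS*, *FOSB* and *EGR3*, the last 3 of them below the expression floor for naming and chosen after their values were seen. *ZFP36* no longer passed when GC and length offsets were added (1.24, adjusted p = 0.0683). Changes in the 2 batches correlated at 0.0026 across 10667 genes, which are not independent replicates, against 0.67 to 0.80 at the later times.

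After 4 h of oscillatory flow *LRRC4* (2.09 ± 0.30), the transcription factor *RFX2* (1.63 ± 0.23) and *PMEPA1* (1.54 ± 0.19) were higher than in static cells without a batch term. After adding batch *HMOX1* (3.79 ± 0.39), *HEY1* (3.47 ± 0.31) and *CYP1B1* (3.44 ± 0.53) had the largest rises. *C10orf10* (-3.61 ± 0.48), *DLL4* (-2.18 ± 0.33) and *PIK3C2B* (-2.15 ± 0.20) had the largest falls. *KLF4* (1.51 ± 0.23) rose and *KLF2* (0.19 ± 0.40) did not pass. In the TGF-beta and BMP list, 6 of 21 rose and 1 fell (14 passed when adjusted over the list alone, camera adjusted p = 2.64e-08, 0.00335 and 0.0587). *SMAD6* (2.33 ± 0.31), *SMAD7* (2.06 ± 0.26) and *ID2* (1.87 ± 0.28) rose. In the Notch and arterial list, 6 of 17 rose and 1 fell (13 passed when adjusted over the list alone, camera adjusted p = 2.64e-08, 0.0245 and 0.0691). *HEY2* (2.18 ± 0.29) rose. The NRF2 (5 of 20 higher), shear-protective (3 of 19 higher), mesenchymal, actin, heat shock and autophagy lists passed with the preset correlation only (adjusted p = 0.117, adjusted p = 0.227, adjusted p = 0.0623, adjusted p = 0.216, adjusted p = 0.316 and adjusted p = 0.262 with an estimated correlation). *EDN1* (0.61 ± 0.14) and *CTGF* (0.73 ± 0.14) rose. 3 genes passed without a batch term, all higher, and 410 with it (228 higher and 182 lower).

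After 12 h of oscillatory flow *CYP1B1* (7.67 ± 1.39), *PTGS2* (4.38 ± 0.46) and *HEY2* (3.39 ± 0.40) had the largest rises over static culture without a batch term. The peptide ligand *APLN* (-3.44 ± 0.51), *DHRS3* (-3.17 ± 0.55) and the protocadherin *PCDH12* (-3.09 ± 0.45) had the largest falls without that term. *CD34* changed by -2.94 ± 0.40, adjusted p = 0.00594 in the fit without batch (-2.66 in batch 1 and -3.14 in batch 2). In the replication list, 25 of 26 fell (26 passed when adjusted over the list alone, camera adjusted p = 1.29e-24, 0.00192 and 0.097). *CDT1* (-2.19 ± 0.31), *E2F1* (-1.88 ± 0.25) and *MCM2* (-1.54 ± 0.19) fell. In the mitosis list, 20 of 26 fell (20 passed when adjusted over the list alone, camera adjusted p = 3.52e-08, adjusted p = 0.249 with an estimated correlation). In the NRF2 list, 13 of 20 rose and 1 fell (15 passed when adjusted over the list alone, camera adjusted p = 8.59e-11, 0.0372 and 0.0958). *SLC7A11* (3.14 ± 0.19), *TXNRD1* (2.10 ± 0.19) and *NQO1* (1.46 ± 0.18) rose. In the TGF-beta and BMP list, 13 of 21 rose and 1 fell (16 passed when adjusted over the list alone, camera adjusted p = 2.45e-08, 0.00192 and 0.0958). *ID2* (2.83 ± 0.29) and *BMPR2* (1.33 ± 0.19) rose. In the cholesterol list, 14 of 24 rose and 1 fell (19 passed when adjusted over the list alone, camera adjusted p = 8.81e-08, adjusted p = 0.0693 with an estimated correlation). The shear-protective list did not pass (4 higher and 4 lower, camera adjusted p = 0.112, adjusted p = 0.393 with an estimated correlation), with *KLF4* (1.41 ± 0.23) higher and *ABCA1* (-0.82 ± 0.25) lower.

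Interferon genes fell at 12 h of oscillatory flow: 17 of 27 fell (23 passed when adjusted over the list alone), with *OAS1* (-4.91 ± 0.78), *IFI44L* (-4.13 ± 0.97), *IFIT1* (-3.57 ± 0.76) and *MX1* (-3.38 ± 0.98) lower. Their median was -2.16 (-0.83 in batch 1 and -3.64 in batch 2; camera adjusted p = 0.00127, adjusted p = 0.683 with an estimated correlation), and 24 were lower in both batches. *F3* (3.20 ± 0.56), *EDN1* (0.81 ± 0.14), *CTGF* (1.03 ± 0.14), *FLT1* (1.68 ± 0.17), *CDH2* (1.13 ± 0.14) and *FN1* (1.33 ± 0.21), the fibronectin gene, rose. *CLDN5* (-3.53 ± 0.41) and *ICAM2* (-2.06 ± 0.24), junction and adhesion genes of endothelium, fell. Both were also lower than static at 12 h of pulsatile flow, in the fit with batch and GC and length offsets. There *CLDN5* changed by -2.76 (adjusted p = 2.52e-05) and *ICAM2* by -0.83 (adjusted p = 0.0149). The YAP and TAZ (7 higher and 1 lower), matrix, actin, Notch and autophagy lists passed with the preset correlation only (adjusted p = 0.315, adjusted p = 0.315, adjusted p = 0.06, adjusted p = 0.301 and adjusted p = 0.315 with an estimated correlation). 143 genes passed without a batch term (63 higher and 80 lower) and 3854 with it (1999 and 1855).

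After 24 h of oscillatory flow *CYP1B1* (7.16 ± 1.35), *PTGS2* (4.93 ± 0.48) and *F3* (4.08 ± 0.69) had the largest rises over static culture without a batch term. *DHRS3* (-3.74 ± 0.57), the metalloprotease *ADAMTS18* (-3.31 ± 0.65) and *APLN* (-2.85 ± 0.50) had the largest falls without that term. *ASS1* (-1.75 ± 0.36) and *CD34* (-2.15 ± 0.39), both higher under pulsatile than oscillatory flow, were lower than static in the fit without batch. In the mitosis list, 26 of 26 fell (26 passed when adjusted over the list alone, camera adjusted p = 6.74e-25, 0.0185 and 0.151). *PLK1* (-2.11 ± 0.23) and *BIRC5* (-2.12 ± 0.24) fell. In the replication list, 23 of 26 fell (23 passed when adjusted over the list alone, camera adjusted p = 3.97e-16, 0.0117 and 0.194). *TYMS* (-1.79 ± 0.17) and *MCM2* (-1.32 ± 0.19) fell. In the NRF2 list, 14 of 20 rose and 1 fell (16 passed when adjusted over the list alone, camera adjusted p = 3.69e-10, 0.0362 and 0.12). *SLC7A11* (3.06 ± 0.19) and *TXNRD1* (2.02 ± 0.19) rose. In the TGF-beta and BMP list, 11 of 21 rose (15 passed when adjusted over the list alone, camera adjusted p = 2.51e-06, 0.0117 and 0.151). The shear-protective (5 higher and 3 lower), cholesterol, Notch, YAP and TAZ, vasoactive and matrix lists passed with the preset correlation only (adjusted p = 0.397, adjusted p = 0.313, adjusted p = 0.129, adjusted p = 0.397, adjusted p = 0.108 and adjusted p = 0.397 with an estimated correlation). The tip cell gene *ESM1* (1.77 ± 0.25), the protease *MMP10* (2.31 ± 0.21), the integrin subunit *ITGAV* (1.61 ± 0.16) and *KLF4* (1.34 ± 0.23) rose. *TMEM88* (-3.24 ± 0.32) and *PLAT* (-1.65 ± 0.22), the tissue plasminogen activator, fell. *KLF2* (-0.18 ± 0.41) and *NOS3* (0.34 ± 0.16) did not pass. 200 genes passed without a batch term (86 higher and 114 lower) and 4093 with it (2161 and 1932).

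**Figure D3:**
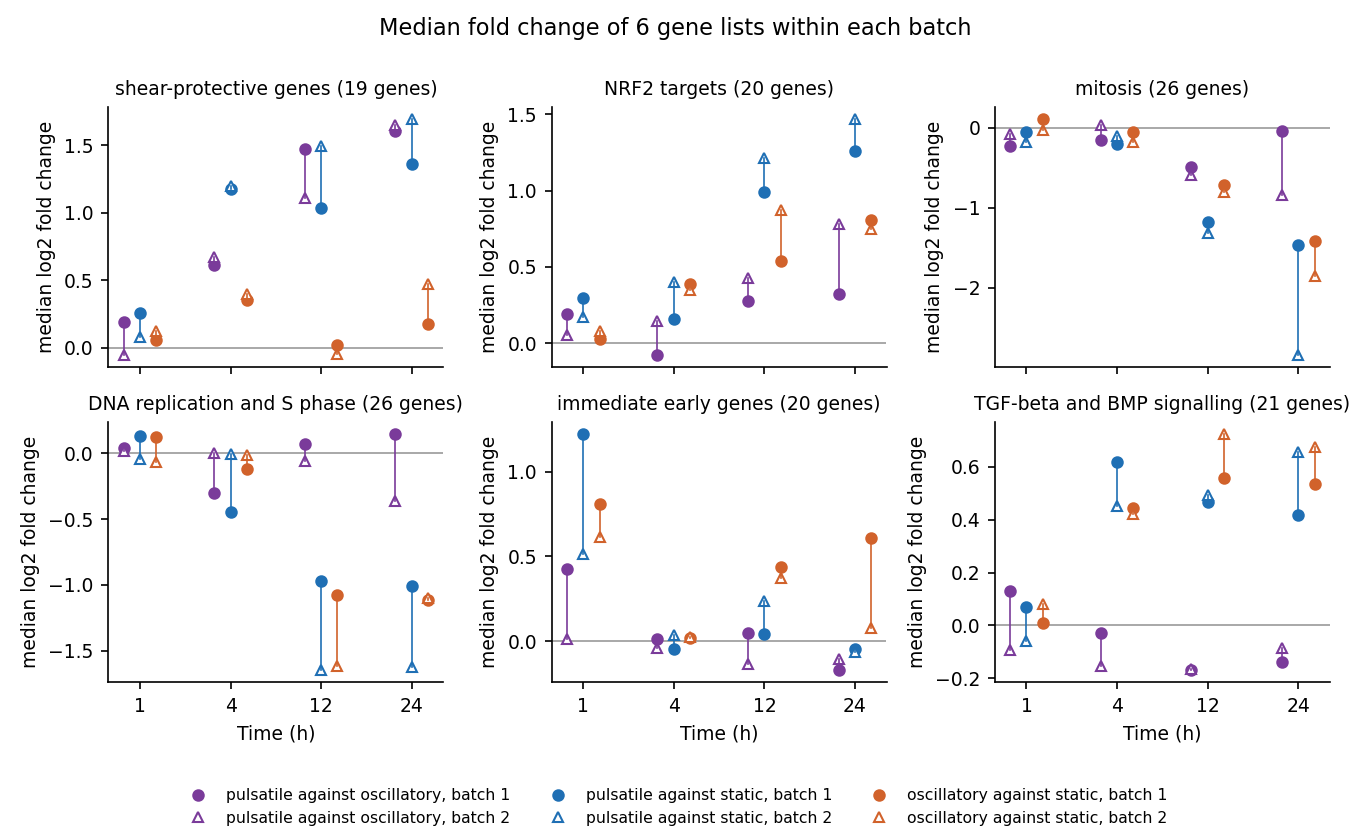
Median log2 fold change (y axis) of 6 gene lists at each time in hours (x axis) within batch 1 (filled circles) and batch 2 (open triangles) for the 3 pairs of flows, with a line joining the batches. Shear-protective genes stood higher under pulsatile than oscillatory flow in both batches from 4 h on, reaching medians of 1.61 and 1.65 at 24 h.

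Averaged over the 4 times and without a batch term, *KLF4* (3.23 ± 0.32), *PTGS2* (2.73 ± 0.42), *F2RL3* (2.36 ± 0.47), the cytokine *IL11* (2.35 ± 0.41) and *HEY2* (2.34 ± 0.37) had the largest rises under pulsatile flow against static culture. *C10orf10* (-3.00 ± 0.31), *ANGPT2* (-1.96 ± 0.36), *ACSM3* (-1.71 ± 0.29), *PPP1R16B* (-1.60 ± 0.33) and the proapoptotic *BCL2L11* (-1.54 ± 0.27) had the largest falls without that term. With batch as a term *CYP1B1* (6.63 ± 1.08), *CYP1A1* (3.36 ± 0.72) and *HMOX1* (3.08 ± 0.38) rose and *KIT* (-2.54 ± 0.38) and *FILIP1* (-1.64 ± 0.24) fell. For oscillatory flow *TIPARP* (1.95 ± 0.26), a target of the aryl hydrocarbon receptor, and *PMEPA1* (1.19 ± 0.17) rose and the kinase *PLK2* (-0.88 ± 0.11) fell without a batch term. In the fit with batch *CYP1B1* (4.90 ± 0.81), *PTGS2* (3.11 ± 0.52), *CYP1A1* (2.50 ± 0.50), *F3* (2.49 ± 0.43) and *RASD1* (2.32 ± 0.38) had the largest rises. *C10orf10* (-2.47 ± 0.35), *DHRS3* (-1.77 ± 0.48), *APLN* (-1.75 ± 0.42), *CLDN5* (-1.60 ± 0.41) and *IFIT1* (-1.49 ± 0.39) had the largest falls. Pulsatile flow changed 105 genes without a batch term (77 higher and 28 lower) and 3747 with it (1963 and 1784). Oscillatory flow changed 4 (3 and 1) and 1920 (1068 and 852). One of those 4 was an unannotated locus with very low counts.

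Pulsatile and oscillatory flow moved many genes the same way against static culture. Their changes over all times correlated at r = 0.70 across 20486 genes without a batch term and 0.68 with it. The comparisons share their static libraries, which alone makes such changes correlate: in simulated unchanged groups that shared static libraries, r averaged 0.51 (highest 0.53 of 20 simulations). The covariance was 0.151 against 0.0251 simulated without a batch term and 0.139 against 0.0228 with it, differences of 0.126 and 0.116. The simulations held no GC or length trend of single libraries, so these differences may be too large. With the static libraries split by batch, so that none was shared, r was 0.44 and 0.51, and within batch 1 and batch 2 alone it was 0.69 and 0.61. Once batch was in the model, 563 genes rose under both flows, where independent calls would give 98.9, and 486 fell under both, against 74.2. In the simulated unchanged groups no gene did either, and the value for independent calls leaves out the shared libraries, so the excess over either is no measure of a shared effect. 7 genes passed in opposite directions.

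Static cells also changed between 1 and 24 h. In the fit without batch *BMP4* (1.89 ± 0.28) rose and *HEY2* (-3.48 ± 0.40), *SMAD7* (-3.11 ± 0.44) and *LRRC4* (-2.88 ± 0.31) fell. After adding batch *C10orf10* (3.46 ± 0.47) rose and *HEY1* (-3.67 ± 0.31) and *ID2* (-3.35 ± 0.30) fell. The falls of *HEY2*, *SMAD7* and *ID2* in static cells may make up part of their rises over static culture at the later times. The TGF-beta and Notch list results against static culture share this limit. Under pulsatile flow *C10orf10* (4.05 ± 0.66), *NQO1* (3.37 ± 0.59) and the cystine transporter *SLC7A11* (2.74 ± 0.47) had the largest rises without a batch term. *HEY1* (-3.81 ± 0.72), the kinase *SIK1* (-3.33 ± 0.41) and *ANGPT2* (-3.32 ± 0.28) had the largest falls without that term. *CYP1B1* (3.90 ± 0.50) and *CYP1A1* (3.38 ± 0.58) rose in the fit with batch. Under oscillatory flow, without a batch term, *TRAF3IP3* (2.94 ± 0.43) and *SLC7A11* (2.63 ± 0.46) rose and *ADAMTS18* (-3.62 ± 0.66), *HEY1* (-3.20 ± 0.70) and *DHRS3* (-2.88 ± 0.55) fell. The endothelial lipase *LIPG* (2.61 ± 0.32) rose and *OAS1* (-3.43 ± 0.67) fell in the fit with batch. Between 1 and 24 h, 6 genes passed in static cells without a batch term (1 higher and 5 lower) and 801 with it. Under pulsatile flow 707 (342 and 365) and 6001 passed, and under oscillatory flow 319 (111 and 208) and 3649. Whether these counts differ between flows was tested only for the pulsatile minus oscillatory shift above.

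Markers of other cell types were present beside the endothelial cadherin *CDH5*, at a mean of 1086 CPM. The highest smooth muscle and fibroblast marker, the pericyte gene *RGS5*, stood close to it (929.8 CPM, with 10 of 12 tested markers at 1 CPM or more). Endothelial cells in culture can also express *RGS5*, and no test here told its source. The highest leukocyte marker was *LAPTM5* (138 CPM, 4 of 14 markers tested) and the highest epithelial marker *KRT19* (7.16 CPM, 5 of 10 tested). Each was the only 1 of its list at 1 CPM or more. None of 10 red cell markers was tested.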

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

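The tests of GC share and gene length, of normalization and of a mislabelled sample were chosen only after the result was seen. The bounds of the GC and length tests at 24 h were also set with the share of genes that still passed already known.

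The difference between pulsatile and oscillatory flow itself changed with time. It shifted between 1 and 24 h for 6 genes without a batch term (187 with it), and it varied over the 4 times for 4 genes (545 with batch). What set these results apart is that the change in the effect was tested directly. *ANGPT2* and *ABCG2* passed both tests, at -2.66 and 3.06 log2 units between 1 and 24 h.

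The many genes called between pulsatile and oscillatory flow at 24 h with batch in the model followed GC share and gene length, which may be technical in part. GC and length do not account for the whole: of 3996 called genes with a GC value, 48.2% still passed with the same sign after the trends were removed. Called genes had a median absolute change of 0.74 log2 units before and 0.47 after, and 3901 kept their sign. The changes also correlated with the difference between batches, at r = 0.67 across genes, and at 0.34 with the trends removed. Normalization stays open: 94% of the called genes passed with the same sign under median-of-ratios size factors, but these shifted the changes by a median of only -0.03 log2 units against a median SE of 0.27, too little to decide. For the genes that no longer passed, a technical trend and a response to flow that tracks gene length cannot be told apart. The length slope was lower in pulsatile than oscillatory libraries in 6 of 8 pairs of the same time and batch and higher in both pairs at 4 h (mean difference -0.139, exact two-sided sign-flip p = 0.0469). That test takes the 8 pairs as independent, though both batches had the same sign at each time, so its p-value may be too small.

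For pulsatile against oscillatory flow over all times, exchanging the flows of both 4 h pairs called 5190 genes with batch in the model, more than the 1602 of the real groups, which points to a structure of the samples. An exchange of the pulsatile and oscillatory labels at 4 h is argued against, since 17 of 19 shear-protective genes were higher under pulsatile flow in both batches at that time. A wrong time or batch label was not tested. GC and length trends, as fitted by the offsets, are argued against as the whole cause as well: with them removed the exchange called 1609 genes against 719. At 4 h the pulsatile minus oscillatory changes correlated with the difference between batches at r = -0.49 across genes, against 0.74, 0.66 and 0.67 at 1, 12 and 24 h (with the trends removed -0.26 against 0.40, 0.37 and 0.34), so the 4 h pairs ran the other way along that difference. What set the 4 h libraries apart stays open, and no biological explanation was tested.

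Other splits of the 16 libraries of each pair of flows were counted. Without a batch term the real groups called 0 genes for pulsatile against oscillatory flow, so every split calls as many by necessity and the count tells nothing about chance. The highest other split called 12199 and followed batch, with 1 library of the other batch among 8. For pulsatile against static flow 105 genes were called in the real groups and 0 in the highest other split (1 of 100 splits as large). For oscillatory against static flow the counts were 4 and 12279 (3 of 100), the latter again a split by batch. These splits ignored batch, over which the real groups were balanced, and most called no gene. Such shares therefore do not exclude chance for either comparison. With batch in the model and flows exchanged only within pairs, 4 of 100 splits called as many genes for pulsatile against oscillatory flow. With batch in the model the real groups called 3747 genes for pulsatile against static flow and 1920 for oscillatory against static flow. The highest other splits called 2005 and 1551, so only the real groups reached these counts among 100 splits. For pulsatile against oscillatory flow, other exchanges called at least as many genes as the real groups, up to 5190. That count does not set flow apart from the structure of the samples. The exchanges take the pairs as independent, though they come from 2 batches, so chance is not excluded for any of the 3 comparisons.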

How the results depend on the processing

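The GC and length offsets and every other setting combined with the batch term were added and so chosen after seeing the data, as was the overlap within each batch. With 2 libraries per group, leaving one out assumes that the lone library left varies like the other groups. The alternatives without a batch term are limited by the spread between batches, which the batch term takes out of the residual. For counts that moved, the cause was not tested, except that the 4 libraries alone and the leave-one-out fits hold fewer samples. The 4 libraries alone do not apply to changes between times, to the F test or over all times. Every setting named before the data were examined was run.

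Without a batch term, genes past the threshold numbered 0, 0, 12 and 22 at 1, 4, 12 and 24 h and 0 over all times for pulsatile against oscillatory flow, 0, 9, 175 and 310 and 105 for pulsatile flow against static culture, and 0, 3, 143 and 200 and 4 for oscillatory flow against static culture. In the same order, with batch as a term there were 14, 3, 857, 4332 and 1602 for pulsatile against oscillatory flow. Pulsatile flow against static culture had 76, 530, 2725, 4163 and 3747, and oscillatory flow 4, 410, 3854, 4093 and 1920. For changes with time, the counts of 6, 707, 319, 6 and 4 without a batch term became 801, 6001, 3649, 187 and 545. These are for static cells, pulsatile and oscillatory flow between 1 and 24 h, the shift in the pulsatile minus oscillatory difference and the F test. Batch thus moved all 20 counts of genes. The number of list tests past the threshold went from 93 to 101 at the preset correlation and from 35 to 11 at an estimated one.

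DESeq2 without a batch term called 55 and 175 at 12 and 24 h and 134 over all times for pulsatile against oscillatory flow. At 1, 4, 12 and 24 h and over all times, against static culture, it called 22, 113, 580, 805 and 817 for pulsatile flow and 2, 70, 573, 639 and 492 for oscillatory flow. Between 1 and 24 h it called 85 for static cells, 1479 for pulsatile and 818 for oscillatory flow. It called 27 for the shift in the pulsatile minus oscillatory difference and, by a likelihood ratio test, 25 for the F test.

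GC and length offsets without a batch term gave 76 at 24 h and 32 over all times for pulsatile against oscillatory flow. Against static culture they gave 2, 69, 498 and 763 at 1, 4, 12 and 24 h and 189 over all times for pulsatile flow. For oscillatory flow they gave 29, 467 and 510 at 4, 12 and 24 h and 23 over all times. Between 1 and 24 h they gave 30 for static cells, 1530 for pulsatile and 843 for oscillatory flow. With batch and the offsets the counts were 3, 8, 650 and 2764 at 1, 4, 12 and 24 h for pulsatile against oscillatory flow, 54, 681, 3276 and 4645 for pulsatile flow against static culture and 3, 588, 3926 and 3769 for oscillatory flow against static culture.

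The stricter filter, which tests fewer genes, gave 34 at 24 h and 10 over all times for pulsatile against oscillatory flow, 25 at 4 h for pulsatile flow against static culture, 5 at 4 h and 11 over all times for oscillatory flow against static culture and 7 for the F test. No filter gave 1 at 4 h and 2 over all times for oscillatory flow against static culture. DESeq2 size factors gave 2 for the F test. The time-averaged contrast of all 24 libraries gave 49 for pulsatile against oscillatory flow and 644 and 432 for pulsatile and oscillatory flow against static culture. In the edgeR fit of the 4 libraries alone no count stayed above 0. This held at 12 and 24 h for pulsatile against oscillatory flow and at 4, 12 and 24 h for each flow against static culture. The fit of 24 libraries had 500 and 1158 genes at an unadjusted p under 0.05 for pulsatile against oscillatory flow at 12 and 24 h.

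Leaving out 1 library without a batch term, the counts ran from 0 to 6 at 12 h and 8 (without oscillatory 24 h replicate 1) to 12 (without pulsatile 24 h replicate 1) at 24 h for pulsatile against oscillatory flow. For pulsatile flow against static culture they ran from 0 to 2 at 4 h, 14 (without static 12 h replicate 2) to 68 (without static 12 h replicate 1) at 12 h and 48 (without pulsatile 24 h replicate 2) to 153 (without pulsatile 24 h replicate 1) at 24 h. For oscillatory flow against static culture they ran from 0 to 1 at 4 h, 7 (without static 12 h replicate 2) to 76 (without static 12 h replicate 1) at 12 h and 13 (without static 24 h replicate 2) to 57 (without static 24 h replicate 1) at 24 h. In each of these the omission of any of the 4 libraries lowered the count by more than 1.5 times. Counts at 1 h, and at 4 h for pulsatile against oscillatory flow, were 0 throughout in edgeR, with 247, 261, 107 and 133 genes at an unadjusted p under 0.05 with no library left out. Between 1 and 24 h the counts ran from 0 to 3 in static cells, 158 to 308 under pulsatile flow and 14 to 71 under oscillatory flow, from 0 to 4 for the shift and from 1 to 4 for the F test. Over all times they ran from 0 to 3 for pulsatile against oscillatory flow, 14 (without static 12 h replicate 1) to 162 (without pulsatile 1 h replicate 1) for pulsatile flow and 0 (without static 4 h replicate 1) to 14 (without static 1 h replicate 2) for oscillatory flow against static culture.

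With batch as a term the same omissions gave 0 to 24, 0 to 2, 249 (without pulsatile 12 h replicate 1) to 651 (without oscillatory 12 h replicate 2) and 1351 (without oscillatory 24 h replicate 2) to 2847 (without oscillatory 24 h replicate 1) genes at 1, 4, 12 and 24 h for pulsatile against oscillatory flow. For pulsatile flow against static culture they gave 6 to 60, 178 to 262, 1315 to 2245 and 2057 to 2739, and for oscillatory flow 1 to 8, 117 to 154, 1323 (without static 12 h replicate 2) to 4579 (without static 12 h replicate 1) and 1798 to 2440. Over all times they gave 398 (without pulsatile 12 h replicate 2) to 3838 (without oscillatory 4 h replicate 1) for pulsatile against oscillatory flow, 2075 to 3990 for pulsatile and 512 to 2628 for oscillatory flow against static culture.

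Of 372 tests of a list in a comparison, 93 passed with the preset correlation, 35 with an estimated correlation, 11 with batch and an estimated correlation, and 12 with GC and length offsets added to these. With the preset correlation 101 passed with batch, 85 with the offsets, 87 with both and 98 with a prior count of 0.5. The correlation of pulsatile with oscillatory changes against static culture moved from 0.70 to 0.44 and 0.51 with static libraries split by batch, and to 0.69 in batch 1 alone and 0.61 in batch 2 alone.

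No change of a named gene past the threshold reversed its sign under any alternative run. Of the values of named genes with batch as a term, 347 kept their sign and side of the threshold with GC and length offsets. Of the rest, 23 no longer passed, 2 newly passed and 13 that passed in neither fit changed sign. Beyond those named in the report at 24 h, the genes that no longer passed were *CREBRF*, *FAM109A*, *FAM212A*, *FAM84B*, *SEMA6D* and *TRIM47* for pulsatile against oscillatory flow at 1 h, *ASPM*, *CENPE* and *KLF2* for pulsatile against oscillatory flow at 12 h, *IER3*, *KLF2* and *NRARP* for pulsatile against static culture at 1 h, *CCL2* for pulsatile against static culture at 12 h and *ZFP36* for oscillatory against static culture at 1 h. With DESeq2 size factors 388 kept them, with DESeq2's test 380, without a filter 388 and with the stricter filter 388. Leaving out 1 library with batch as a term, 1903 values kept them and 273 no longer passed.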

Other observations

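The aryl hydrocarbon receptor genes and the interferon tests below were chosen only after the result was seen. The former are 6 genes that the receptor is known to induce, and of these only *CYP1B1* under pulsatile flow passed at 1 h with batch in the model. At 12 h of pulsatile flow, with batch in the model, *CYP1B1* was higher by 10.09 ± 0.71, *ALDH3A1* by 6.96 ± 0.54, *CYP1A1* by 5.50 ± 0.65, the receptor's repressor *AHRR* by 2.65 ± 0.27, *TIPARP* by 2.45 ± 0.27 and *NQO1* by 2.40 ± 0.19 log2 units (± SE, n = 2 libraries per group). At 12 h of oscillatory flow the same genes were higher by 7.73 ± 0.68, 4.29 ± 0.59, 3.93 ± 0.60, 2.33 ± 0.27, 2.71 ± 0.27 and 1.46 ± 0.18, in that order. Without a batch term *TIPARP*, *CYP1B1* and *AHRR* passed under both flows and *ALDH3A1* under pulsatile flow. *CYP1B1* and *ALDH3A1* had few counts in static libraries, so the sizes of their fitted changes depend on the prior count. In static cells *CYP1B1* (-3.28 ± 0.60) and *TIPARP* (-1.99 ± 0.26) fell between 1 and 24 h with batch in the model, so a decline in static culture may make up part of the gap. No test here tells flow from other differences between the static and flow cultures, such as medium or device. *CYP1A1* and *CYP1B1* are also in the shear-protective list, and *NQO1* in the NRF2 list.

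Interferon-induced genes differed between batches. The median log2 CPM of the list was 0.26 to 1.58 across the 12 libraries of batch 1 and 1.90 to 5.68 across those of batch 2. At 12 h of oscillatory flow the list was lower than static. GC and length trends are argued against, as the list's median stayed at -1.96 with them removed. Within batch 1 alone, 24 of 27 members were lower. That compares 1 library with 1, at low list medians (1.57 log2 CPM static, 0.26 oscillatory). The members also vary together, so their number cannot exclude a fall in batch 2 alone. At 12 h of pulsatile flow 15 of 27 were lower within batch 1, which leaves open whether the fall was in batch 2 alone. A response of these genes to flow may remain as a hypothesis for oscillatory flow at 12 h. The list's camera test did not hold with an estimated correlation (adjusted p = 0.683 with an estimated correlation; adjusted p-values over its alternatives ran from 7.54e-10 to 0.683).

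The batches differed in composition. The slope of log2 expression deviations with gene length was 0.20 to 0.46 per doubling in batch 1 and -0.57 to -0.12 in batch 2. Genes of the mitochondrial genome took 4.86% to 7.12% of the counts in batch 1 and 2.68% to 4.42% in batch 2. The mean deviation of ribosomal protein genes was -1.49 to -0.58 log2 units in batch 1 and 0.42 to 1.75 in batch 2.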
